A study of Mus musculus with 28 samples.

How the data were processed

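RNA that came down with the kinase PKR was measured in mouse embryonic fibroblasts. PKR is a kinase that is activated by double-stranded RNA. Per the labels, the cells carried either wild-type PKR (WT) or PKR mutated in each of its double-stranded RNA-binding motifs (RM), and were given mock treatment or 0.1 mM palmitic acid, a saturated fatty acid. PKR was immunoprecipitated, and the bound RNA was extracted with Trizol, fragmented and made into libraries with a small RNA kit. The labels call the libraries of a group biological replicates. Datasets A and B hold 3 libraries in each of the 4 groups, and dataset C holds 1 library per group. The columns of dataset B carry the mark 2hr, whose meaning the labels do not give.

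Per the submitters' processing notes, bases were called with CASAVA 1.7.0 and 1.8.2, reads were aligned with Novoalign, and the genome build was mm9. The Novoalign version, the counting tool, the use of strand in counting and the tool of the authors' own test are not given in the sources used here. The deposited tables of datasets A and B give whole-number counts per feature and library, and the deposited tables of dataset C give counts on each strand, which were summed. The authors also gave a log2 ratio per feature, and a false discovery rate on what was read here as a score of 10 times its negative log10, so that 13.01 stands for 0.05. These tables were used only for the authors' own numbers of features past that score. Each table holds 30210 features. There were 32 columns of counts used and 52 other columns of values per sample that were not used.

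Positions are those of the files on mm9, counted from 1. The reference annotation at hand, GENCODE M21, belongs to another build and was used for gene names only. Of 29777 Ensembl identifiers, 25755 were found in it. Features with another identifier keep the name in the files, and Ctgf in the files is named Ccn2 here. Because the use of strand in counting is not stated, overlapping and antisense features cannot be told apart. This holds for the snoRNAs that lie in introns of host genes, for mt-Nd5 and mt-Nd6, which overlap on opposite strands, and for mt-Ti, which overlaps mt-Nd1 and mt-Tq. Near-identical features were sought as features whose counts differed by at most 3% or 3 counts in the libraries, with a mean of at least 50 counts. There were 8 such sets with 49 features, and the largest held 32 ribosomal RNA features. Members of these sets are uncertain.

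The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, robust estimation and the filter of filterByExpr, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a single feature given in the text comes from this test unless another is named. All 12 libraries of a dataset were fitted together with 1 mean per group, and the average over datasets A and B was taken from a fit of 24 libraries with 8 group means. The fits tested 11328 features in dataset A, 12466 in dataset B and 12683 in both. Log2 fold changes are given with their standard error (SE), and levels as CPM, counts scaled to a common library size, after TMM scaling with the standard deviation (SD) over 3 libraries. Tables of dataset C were only described: log2 ratios were taken between CPM values with a prior count of 1 for features with a mean of at least 10 counts.

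Gene lists were fixed, with the tests, the alternatives and the rule for named genes, before the data were examined. They cover C/D box and H/ACA box snoRNAs, small Cajal body RNAs (scaRNAs), RNAs of the imprinted Dlk1-Dio3 cluster, the snoRNAs of the Rpl13a gene and snoRNA host genes. The spliceosomal list was matched by name and also takes in Rnu3a and Rnu73b, which are small nucleolar RNAs. Further lists are other structured small RNAs, miRNAs, mitochondrially encoded RNAs, ribosomal protein mRNAs, replication-dependent histone mRNAs, interferon-stimulated genes, the integrated and endoplasmic reticulum (ER) stress response, fatty acid response, cholesterol synthesis, and markers of fibroblasts, of macrophages and lymphocytes, of epithelium and of endothelium. Lists were tested with camera at a preset correlation of 0.01 and an estimated correlation, and with fry, a rotation test. Benjamini-Hochberg adjustment was over the lists of a comparison. For dataset C, a list's median was given its percentile among 10000 random lists matched on mean counts in 20 bins. Shares of RNA classes were compared by exact permutation tests, two-sided, whose smallest possible p with 3 against 3 libraries is 0.1.

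The named features are, per comparison, the 10 highest and the 10 lowest log2 fold changes among features past the threshold with a mean of at least 10 counts in the higher group and no overlap of the groups' libraries. If none passed, the 5 smallest p in each direction were eligible. Up to 4 members of each list with the smallest p, the PKR transcript, the Rpl13a and Dlk1-Dio3 snoRNAs and the 5 most abundant features of each dataset were added. The text takes its examples from these and leaves out features close to 0 counts in a group. A result on 1 named feature is not reported here.

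Alternatives were RLE scaling, scaling by total counts, no count filter, a replicate block, DESeq2 1.42.0, fits of only the groups compared, leaving out each library in turn, the estimated correlation, class shares without mitochondrial and ribosomal RNA, and other prior counts and TMM scaling in dataset C. After the data were seen, fits with 1 feature per near-identical set, fits without replicates 2 and 3 of the RM palmitate group of dataset B, a snoRNA list by the class named in the files and a list of features of at most 300 nt other than snoRNAs were added. Leaving out each library for the gene lists and class shares was added then too, as was a list of S-phase genes other than histones. A fit without those 2 libraries leaves that group with 1 library, which is then assumed to vary like the other groups.

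Checked on counts simulated from the real means and library sizes, the test called 40.3% of 2-fold changes and 89.4% of 4-fold changes for WT palmitate against mock in dataset A (11160 features tested), and 64.2% and 98.5% in dataset B (12365 features tested). For the interaction of genotype and palmitate, the shares were 7.5% and 66.7% in dataset A and 19.4% and 83.3% in dataset B. Depth is given as the total of the deposited counts per library. Reads copied by PCR are not independent molecules, so that the 95% intervals given for single libraries cover counting error only. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.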

Results

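RNA recovered with wild-type PKR (WT) or PKR mutated in its RNA-binding motifs (RM) was counted in mouse embryonic fibroblasts. Cells were mock-treated or given 0.1 mM palmitate. With no input or control precipitate among the samples, RNA abundance, PKR binding and background cannot be told apart. The series asks which RNAs are enriched with WT PKR after palmitate. Its title concerns small nucleolar RNAs (snoRNAs), which guide ribosomal and spliceosomal RNA modification. Datasets A and B held 3 libraries per group, and C, only described, 1.

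In dataset A the total counts of replicates 1, 2 and 3 were 3552968, 4277434 and 3927988 for WT mock, 7555175, 5185248 and 3249858 for WT palmitate, 8036622, 6243069 and 5025829 for RM mock, and 6851012, 254762 and 5834156 for RM palmitate. Dataset B had totals of 6619405, 6169796 and 5380492 for WT mock, 5800843, 3543807 and 5801911 for WT palmitate, 7122087, 7046318 and 3830243 for RM mock, and 3490435, 2204502 and 2696431 for RM palmitate. The libraries of dataset C held 7462653 counts for WT mock, 7739939 for WT palmitate, 10109466 for RM mock and 11658726 for RM palmitate. RM palmitate replicate 2 of dataset A was the shallowest library, and its Spearman correlation with its group was 0.725 to 0.746 across features. RM palmitate replicates 2 and 3 of dataset B stood apart with TMM factors of 0.82 and 0.637. The biological coefficient of variation was 0.22 in dataset A and 0.191 in dataset B. No pair of libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 4.85.

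Lars2 was most abundant, at a mean of 5.07% of counts in A, 3.28% in B and 10.59% in C. Whether these are reads of its mRNA was not tested. Next in A were n-R5-8s1, a 5.8S ribosomal RNA (4.14%), Gm25878 (2.95%), ENSMUSG00000090867 (2.68%) and the C/D box snoRNA Snord49a (2.32%). In B they were Myh9 (1.58%), the mitochondrial ribosomal RNAs mt-Rnr2 (1.55%) and mt-Rnr1 (1.35%), and ENSMUSG00000093337 (1.23%). In C ENSMUSG00000093337 had 4.19%, n-R5-8s1 2.57%, mt-Rnr2 1.91% and ENSMUSG00000070243 1.65%.

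The PKR transcript Eif2ak2 (chr 17, 79251904 to 79281913, minus strand, mm9) was counted in all 4 groups of datasets A and B. It had 8.24 ± 1.42 CPM in WT mock, 10.1 ± 4.62 in WT palmitate, 8.89 ± 2 in RM mock and 14.3 ± 4.27 in RM palmitate of dataset A (SD, n = 3). In dataset B the levels were 7.98 ± 0.72, 8.33 ± 1.18, 10.3 ± 0.173 and 16.8 ± 6.4 CPM in the same order. WT and RM did not differ past the threshold in mock, with a log2 fold change of -0.10 in dataset A (adjusted p = 0.898) and -0.37 in dataset B (adjusted p = 0.287). Under palmitate in dataset B the transcript was lower with WT than with RM by -0.96 ± 0.25 (SE, adjusted p = 0.0281, 0.000803 to 0.76 over the alternatives, the highest without RM palmitate replicates 2 and 3). The call held in 6 of 14 alternatives and ended without RM palmitate replicate 2 (adjusted p = 0.093) or 3 (adjusted p = 0.161) and without WT palmitate replicate 1, 2 or 3 (adjusted p = 0.113, 0.0575 and 0.0825). Averaged over both datasets it rose with palmitate and RM by 0.60 ± 0.19 (adjusted p = 0.0482, 0.00763 to 0.635 over the alternatives), a call that held in 5 of 20 alternatives. Of the 12 fits that left out a library, it held in those without RM mock replicate 2 of A (adjusted p = 0.0428), RM palmitate replicate 1 of A (adjusted p = 0.021) and RM palmitate replicate 1 of B (adjusted p = 0.00763), and ended without any other, with adjusted p = 0.052 to 0.27. Under palmitate it was lower with WT than with RM by -0.71 ± 0.20 (adjusted p = 0.0249, 0.0035 to 0.46 over the alternatives), held in 10 of 20 alternatives. That call ended without WT palmitate replicate 1 or 2 of A (adjusted p = 0.0526 and 0.0677), RM palmitate replicate 3 of A (adjusted p = 0.152), WT palmitate replicate 1 or 3 of B (adjusted p = 0.0572 and 0.0523) and RM palmitate replicate 2 or 3 of B (adjusted p = 0.0597 and 0.0972). In dataset C it had 1.88 and 1.55 CPM with WT and 10.7 and 5.92 CPM with RM, for mock and palmitate. The mutant differs by point mutations, so these levels cannot check the labels, and the gene overlaps n-R5s29 and ENSMUSG00000085149 on the other strand.

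H/ACA box snoRNAs, which guide pseudouridylation, had their lowest mean share of counts among the groups of datasets A and B in WT mock of B. Their share there was 0.111% ± 0.0111, against 0.295% ± 0.0669 in WT palmitate, 0.283% ± 0.00905 in RM mock and 0.315% ± 0.0296 in RM palmitate (SD, n = 3). The ratio of palmitate to mock with WT was 2.66, all 3 palmitate libraries lying above all 3 mock libraries (exact permutation p = 0.1, the smallest possible, 0.3 adjusted over 72 tests). Mitochondrially encoded RNA took 7.7% ± 3.26 of counts in RM palmitate of dataset B and 2.37% ± 1.02 in RM mock (ratio 3.25, exact permutation p = 0.1, 0.3 adjusted). RM palmitate replicate 1 had 4.44% (95% binomial interval 4.42 to 4.46), and replicates 2 and 3, which stood apart, had 7.69% (7.66 to 7.73) and 11% (10.9 to 11). C/D box snoRNAs, which guide ribose methylation, took a larger share in dataset A than in B. In A their share was 7.98% ± 2.88 in WT mock, 10.5% ± 5.64 in WT palmitate, 15.4% ± 4.26 in RM mock and 7.61% ± 4.08 in RM palmitate. In B it was 0.949% ± 1.07, 0.957% ± 0.231, 1.13% ± 0.212 and 1.08% ± 0.178 in the same order, and the ratio of WT palmitate to mock there was 1.01 (exact permutation p = 1), or 2.91, 0.75 and 0.771 without WT mock replicates 1, 2 and 3.

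**Figure D1:**
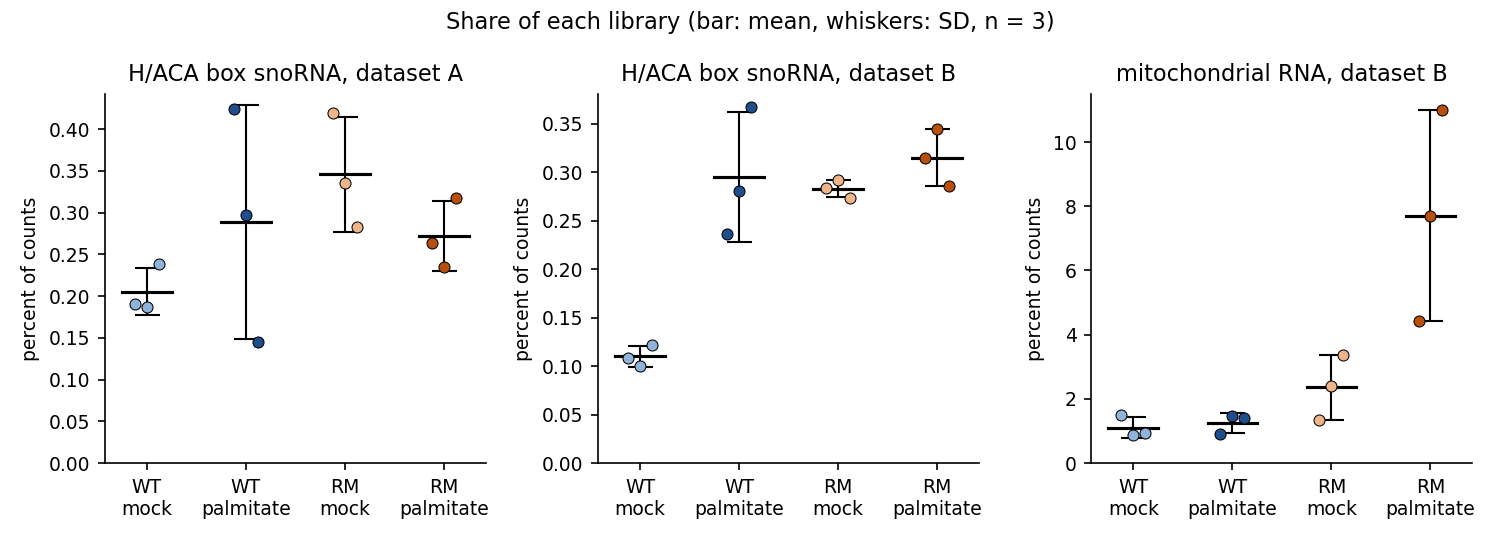
Percent of each library's counts (y axis) that fell in H/ACA box snoRNAs in datasets A and B and in mitochondrially encoded RNA in dataset B, for the 4 groups (x axis). Points are libraries, bars means and whiskers SD (n = 3), and the WT mock libraries of dataset B lie lowest for H/ACA box snoRNAs at 0.111% ± 0.0111.

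With WT PKR in dataset A, palmitate raised Angptl4, a target of fatty acid-activated nuclear receptors, from 5.46 ± 1.91 to 26.5 ± 3.1 CPM (SD, n = 3). Its log2 fold change was 2.25 ± 0.26 (SE, adjusted p = 0.000402). Ccn2, which encodes a matricellular growth factor, rose from 2.17 ± 0.814 to 14.8 ± 1.89 CPM, by 2.70 ± 0.35 on the log2 scale (6.48-fold, adjusted p = 0.000728). Skil, a repressor of TGF-beta signalling, rose by 1.60 ± 0.20, and the transcription factor Osr2 fell, with -1.63 ± 0.20 (adjusted p = 0.000434 for both). These 4 transcripts were called in each of the 6 fits that left out a library. edgeR and DESeq2 each called 0 C/D and 0 H/ACA box snoRNAs, with 3 and 9 at an unadjusted p under 0.05. The values were positive for 74 of 75 C/D box snoRNAs, with a median of 0.57 (camera adjusted p = 2.23e-06, adjusted p = 0.591 with an estimated correlation), and for 37 of 37 H/ACA box snoRNAs, with a median of 0.72 (camera adjusted p = 8.23e-08, adjusted p = 0.591 with an estimated correlation). Snora5c had 1.55 ± 0.46 (adjusted p = 0.18) and Snord64 had 1.84 ± 0.67 (adjusted p = 0.282). Without WT palmitate replicate 1 the C/D median was 0 (camera adjusted p = 0.994), the H/ACA median 0.25 (camera adjusted p = 0.256) and the value of Snord64 0.98 (adjusted p = 0.634). Without WT palmitate replicate 3 the medians were 1.01 and 1.08, and without WT mock replicate 3 the C/D median was 1.01. None of the 18 cholesterol synthesis genes was called over all features, and 5 were lower adjusted over the list alone, with a list median of -0.56 (camera adjusted p = 1.22e-07, adjusted p = 0.296 with an estimated correlation).

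edgeR called 38 features in this comparison, 27 higher and 11 lower, and DESeq2 called 35, 30 higher and 5 lower. The authors' deposited table holds 181 features past its score, 148 higher and 33 lower. The count was 81 without WT palmitate replicate 1, 7 without WT palmitate replicate 2, and 11, 6 and 8 without WT mock replicates 1, 2 and 3. Scaling by total counts gave 6 features (4 higher, 2 lower) and moved the median of all features by -0.14.

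With RM PKR in dataset A, Angptl4 also rose with palmitate, from 5.78 ± 0.787 to 40.9 ± 15.7 CPM (log2 fold change 2.59 ± 0.25, adjusted p = 1.71e-05). The chromatin remodelling subunit Baz1a rose by 1.54 ± 0.24 (adjusted p = 0.00511), and the orphan nuclear receptor Nr4a1 rose by 1.83 ± 0.32 (adjusted p = 0.00991, 1.03e-07 to 0.121 over the alternatives, the highest without RM palmitate replicate 3). Osr2 had -1.47 ± 0.21 (adjusted p = 0.00225, 6.97e-06 to 0.0594 over the alternatives, the highest when scaled by total counts). No C/D box snoRNA was called, 0 by edgeR and 0 by DESeq2, 10 having an unadjusted p under 0.05, and the list's median was -0.80 (camera adjusted p = 1.71e-06, adjusted p = 0.822 with an estimated correlation). The C/D median was -0.26 without RM mock replicate 1 (camera adjusted p = 0.122).

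With RM in dataset A edgeR called 54 (36 higher, 18 lower), and DESeq2 called 45 (42 higher, 3 lower). With total counts for scaling, 12 were past the threshold (12 higher, 0 lower). The authors' deposited table holds 77 features past its score, 30 higher and 47 lower. Without RM mock replicates 1, 2 and 3 the counts were 9, 5 and 29, and without RM palmitate replicates 1, 2 and 3 they were 28, 127 and 31.

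The interaction asks whether palmitate changed an RNA more with WT than with RM PKR. In dataset A edgeR and DESeq2 each called 0 features, with 469 features at an unadjusted p under 0.05. The palmitate effect was more positive with WT for 74 of 75 C/D box snoRNAs, with a median difference of 1.27 on the log2 scale (camera adjusted p = 3.54e-22, adjusted p = 0.54 with an estimated correlation). For 36 of 37 H/ACA box snoRNAs it was also more positive, with a median of 1.12 (camera adjusted p = 3.26e-11, adjusted p = 0.54 with an estimated correlation). Single snoRNAs had large errors, 2.76 ± 0.91 for Snord64 and 1.70 ± 0.60 for Snora5c (adjusted p = 0.981 for both). The 4 snoRNAs of the Rpl13a gene, Snord32a, Snord33, Snord34 and Snord35a, had a median of 1.32 (camera adjusted p = 0.00583, adjusted p = 0.54 with an estimated correlation). Without WT palmitate replicate 1 the C/D, H/ACA and Rpl13a medians were 0.74, 0.65 and 0.81. The Rpl13a list was then not past the threshold (camera adjusted p = 0.125), nor was it without RM mock replicate 1, where its median was 0.71.

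Without palmitate, most mitochondrially encoded RNAs were higher with WT than with RM in dataset A. Of 36 tested, 23 were called higher and 0 lower, 27 higher adjusted over the list alone, and the median was 2.22 (camera adjusted p = 3.29e-55, adjusted p = 0.0387 with an estimated correlation). Their summed share of counts was 1.82% ± 0.474 with WT and 1.32% ± 0.501 with RM (SD, n = 3, ratio 1.38), a difference within the spread of libraries (exact permutation p = 0.2, 0.497 adjusted over 72 tests). The complex I transcript mt-Nd5 (chr M, 11742 to 13565, overlapping mt-Nd6) had 1120 ± 169 CPM with WT and 34.5 ± 7.68 with RM (SD, n = 3). Its log2 fold change was 5.02 ± 0.50 (adjusted p = 2.83e-06). The isoleucine transfer RNA mt-Ti (chr M, 3706 to 3774, overlapping mt-Nd1 and mt-Tq) had 299 ± 34.5 and 6 ± 1.75 CPM, 5.63 ± 0.46 (adjusted p = 5.56e-07). Lars2, not on this list, had 111000 ± 12600 CPM against 17200 ± 960 (2.69 ± 0.58, adjusted p = 0.00939). Adjusted p was 6.52e-16 to 0.0793 over the alternatives, highest without RM mock replicate 2. Of 17 interferon-stimulated genes 6 were higher with WT over all features and 9 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 1.95e-08, adjusted p = 0.0492 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, had 11.1 ± 3.3 CPM with WT and 2.48 ± 0.985 with RM (2.18 ± 0.31, adjusted p = 0.000207), and Ifit3 had 2.14 ± 0.33 (adjusted p = 0.000385). Replication-dependent histone mRNAs had 7 of 62 members higher, 15 adjusted over the list alone (camera adjusted p = 1.03e-09, adjusted p = 0.705 with an estimated correlation), among them Hist1h4c with 1.67 ± 0.27 (adjusted p = 0.000818).

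In all, edgeR called 424 features between the mock groups of dataset A, 343 higher and 81 lower with WT, and DESeq2 called 302. The count was 229 and 200 without WT mock replicates 1 and 2, and 247, 207 and 273 without RM mock replicates 1, 2 and 3. Total counts as the scale gave 240 and moved the median of all features by -0.19.

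Under palmitate in dataset A, 18 of 36 mitochondrially encoded RNAs and 6 of 17 interferon-stimulated genes were higher with WT than with RM. mt-Nd5 had 1220 ± 572 CPM with WT and 36.5 ± 18.8 with RM (4.98 ± 0.51, adjusted p = 1.03e-05). Of the mitochondrially encoded RNAs 26 were higher adjusted over the list alone, with a median of 2.02 (camera adjusted p = 6.05e-38, adjusted p = 0.0584 with an estimated correlation). Their share of counts was 1.7% ± 0.515 with WT and 1.58% ± 0.636 with RM (SD, n = 3, exact permutation p = 0.9). Of the interferon-stimulated genes 12 were higher adjusted over the list alone, with a median of 0.99 (camera adjusted p = 2.02e-11, adjusted p = 0.0463 with an estimated correlation), or 1.64 without RM palmitate replicate 1. Ifit1 had 2.56 ± 0.36 (adjusted p = 0.000228). Mir23a and Mir27a, members of 1 miRNA cluster, were lower with WT, with -1.94 ± 0.27 (adjusted p = 0.000219) and -2.28 ± 0.39 (adjusted p = 0.00213). Histone mRNAs had 2 of 62 members higher, also 2 adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.212). Of 178 miRNAs, 11 were called lower and 2 higher, 20 and 4 adjusted over the list alone. With edgeR 0 C/D and 0 H/ACA box snoRNAs were called, with 11 and 10 at an unadjusted p under 0.05, and DESeq2 called 1 and 0. The C/D median was 0.68 (camera adjusted p = 0.000647, adjusted p = 0.842 with an estimated correlation) and the H/ACA median 0.69 (camera adjusted p = 0.0264, adjusted p = 0.842 with an estimated correlation), both being 0.1 without WT palmitate replicate 1 (camera adjusted p = 0.974 and 0.921), where the H/ACA test turned downward. The H/ACA list was also not past the threshold without RM palmitate replicate 1 or 3 (camera adjusted p = 0.0587 and 0.13).

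This comparison had 388 called features, 282 higher and 106 lower with WT, and 350 by DESeq2. Scaling by total counts gave 521, of which 134 were higher and 387 lower, with the median of all features moved by -0.41. The count was 759 and 212 without WT palmitate replicates 1 and 2, and 201, 612 and 235 without RM palmitate replicates 1, 2 and 3.

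With WT PKR in dataset B, palmitate raised Angptl4, Nr4a1 and most H/ACA box snoRNAs. Of 37 H/ACA box snoRNAs, 32 rose and 0 fell, 33 and 0 adjusted over the list alone, with a median log2 fold change of 1.60 (camera adjusted p = 8.98e-44, adjusted p = 0.0424 with an estimated correlation). Snora23, in an intron of Ipo7 (chr 7, 117189878 to 117190061), rose from 10 ± 1.66 to 31.2 ± 5.01 CPM (SD, n = 3), by 1.64 ± 0.16 (adjusted p = 1.86e-05). Snora64, within Rps2 (chr 17, 24857717 to 24857850), rose by 1.67 ± 0.20 (adjusted p = 0.000274). Of 74 C/D box snoRNAs, 31 rose and 0 fell, 34 and 0 adjusted over the list alone, with a median of 0.93 (camera adjusted p = 8.36e-19, adjusted p = 0.207 with an estimated correlation). Their summed share had a ratio of 1.01 (exact permutation p = 1). Snord118, the U8 snoRNA of ribosomal RNA processing (chr 11, 68886929 to 68887063), rose from 212 ± 25.7 to 685 ± 252 CPM, by 1.69 ± 0.23 (adjusted p = 0.000317). Snord33 of the Rpl13a gene (chr 7, 52382234 to 52382317) rose from 16.6 ± 2.34 to 45.4 ± 13.3 CPM, by 1.46 ± 0.22 (adjusted p = 0.000976). It was the called member of the 4 Rpl13a snoRNAs, of which 2 were higher adjusted over the list alone (median 0.90, camera adjusted p = 0.00699, adjusted p = 0.295 with an estimated correlation). The summed share of the 4 was 0.0261% ± 0.0296 in WT mock and 0.0289% ± 0.00819 in WT palmitate (SD, n = 3, exact permutation p = 1), WT mock replicate 1 lying above each palmitate library with 0.0602% (95% binomial interval 0.0583 to 0.0621). Without that library the Rpl13a and C/D medians were 1.61 and 1.43, and without WT mock replicate 3 the Rpl13a median was 0.80 (camera adjusted p = 0.058). The WT mock libraries, whose mean H/ACA share lay below that of both RM groups, also enter the mock comparison.

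Among scaRNAs, which guide modification of spliceosomal RNA, 3 of 9 were higher in this comparison, 4 adjusted over the list alone, with a median of 1 (camera adjusted p = 8e-05, adjusted p = 0.207 with an estimated correlation), and Scarna6 rose by 1.51 ± 0.22 (adjusted p = 0.000566). In the Dlk1-Dio3 cluster 3 of 5 RNAs were higher, 4 adjusted over the list alone, with a median of 1.30 (camera adjusted p = 7.25e-05, adjusted p = 0.112 with an estimated correlation). The long noncoding RNA Meg3 rose from 44.1 ± 24.3 to 253 ± 98.7 CPM by 2.53 ± 0.41 (adjusted p = 0.00513, 9.43e-11 to 0.0521 over the alternatives, the highest in a fit of the WT groups only), and the snoRNA AF357341 by 1.38 ± 0.26 (adjusted p = 0.00463). In the spliceosomal list 3 of 7 members were higher, also 3 adjusted over the list alone (camera adjusted p = 0.000304, adjusted p = 0.207 with an estimated correlation). These included, beside Rnu2-10, the small nucleolar RNAs Rnu73b, with 1.40 ± 0.15 (adjusted p = 5.17e-05), and Rnu3a, with 1.95 ± 0.40 (adjusted p = 0.00509, 9.84e-06 to 0.0806 over the alternatives, the highest in the same fit). Of 17 snoRNA host genes 2 were higher, also 2 adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.578). The 174 miRNAs had 7 members higher and 2 lower, 6 and 0 adjusted over the list alone. Their median was -2.02 (camera adjusted p = 1.28e-06, adjusted p = 0.728 with an estimated correlation). It was -0.28 without WT mock replicate 1 (camera adjusted p = 0.301).

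Among mRNAs in the same comparison, Nr4a1 rose from 2.23 ± 0.27 to 25.0 ± 7.23 CPM (3.49 ± 0.24, 11.24-fold, adjusted p = 4.17e-07) and Angptl4 from 14.2 ± 1.84 to 66.9 ± 7.14 CPM (2.24 ± 0.16, adjusted p = 4.17e-07). Txnip, an inhibitor of thioredoxin, fell from 83.3 ± 5.32 to 23.8 ± 0.37 CPM (-1.81 ± 0.14, adjusted p = 2.1e-06). Of 63 replication-dependent histone mRNAs, 27 fell and 0 rose, 41 and 0 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 8.36e-19, adjusted p = 0.207 with an estimated correlation). Hist1h3f fell from 42.1 ± 13.4 to 18.8 ± 1.55 CPM (-1.16 ± 0.19, adjusted p = 0.00127). Of 18 cholesterol synthesis genes, 12 fell and 0 rose, 15 lower and 1 higher adjusted over the list alone, with a median of -0.49 (camera adjusted p = 2.39e-08, adjusted p = 0.0111 with an estimated correlation). Idi1, the isopentenyl diphosphate isomerase, had -0.98 ± 0.15 (adjusted p = 0.000825), and Stard4, a sterol transport protein, had -0.69 ± 0.11 (adjusted p = 0.000747). In the integrated and ER stress response 1 of 21 genes fell, Herpud1 of ER-associated degradation, 8 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.00538, adjusted p = 0.207 with an estimated correlation). The 18 fatty acid response genes had 2 higher and 3 lower members, also 2 and 3 adjusted over the list alone. Angptl4 and Ppard, a fatty acid-activated nuclear receptor, rose (Ppard by 0.81 ± 0.18, adjusted p = 0.00661), and Fabp5, Scd1 and Scd2 fell.

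edgeR called 1938 features with WT in dataset B, 1175 higher and 763 lower, and DESeq2 called 1654. The authors' deposited table holds 1967 past its score, 1206 higher and 761 lower. The count fell to 1075 without WT mock replicate 2 and to 1275, 1163 and 923 without WT palmitate replicates 1, 2 and 3, and scaling by total counts gave 1084 (724 higher, 360 lower). Each feature given here with its SE was called in each of the 6 fits that left out a library.

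**Figure D2:**
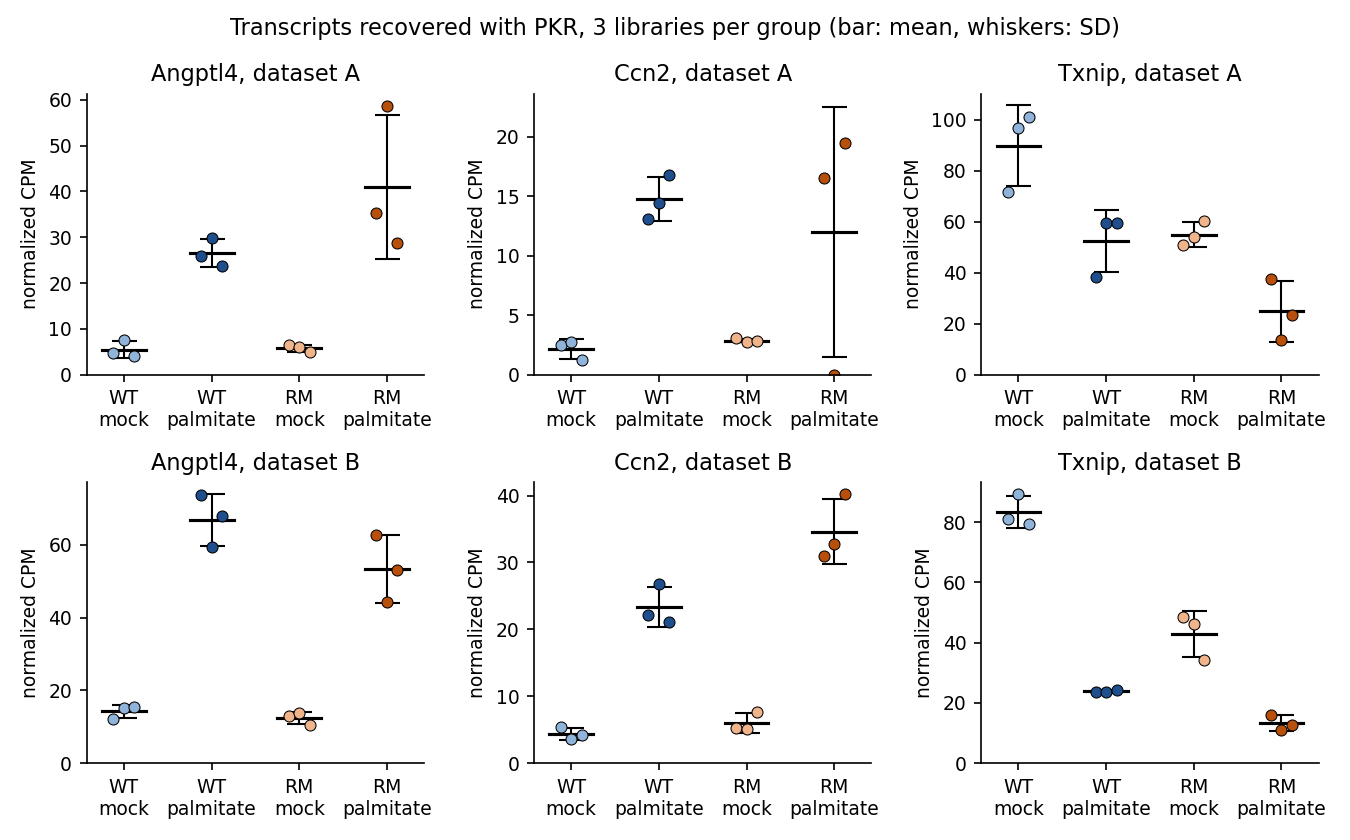
Level of Angptl4, Ccn2 and Txnip in CPM after TMM scaling (y axis) in the 4 groups (x axis) of datasets A and B. Points are libraries, bars means and whiskers SD (n = 3), and in dataset B Angptl4 stood at 14.2 ± 1.84 CPM in WT mock and 66.9 ± 7.14 in WT palmitate.

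With RM PKR in dataset B, palmitate raised Angptl4 from 12.4 ± 1.7 to 53.4 ± 9.24 CPM (2.10 ± 0.16, adjusted p = 2.37e-06) and lowered Txnip from 43.0 ± 7.64 to 13.3 ± 2.52 CPM (-1.66 ± 0.17, adjusted p = 3.07e-05). Both were called in each of the 14 alternatives run, also without RM palmitate replicates 2 and 3. Of 37 H/ACA box snoRNAs 7 rose, 15 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 4.38e-10, adjusted p = 0.273 with an estimated correlation). Of 74 C/D box snoRNAs 3 rose, 1 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 1.43e-06, adjusted p = 0.403 with an estimated correlation). Snora23 rose from 30.6 ± 2.26 to 53.5 ± 6.39 CPM (0.80 ± 0.15, adjusted p = 0.00919), with 0.000781 to 0.333 over the alternatives, the highest without RM palmitate replicates 2 and 3, and 0.0502 without RM mock replicate 1. Mitochondrially encoded RNAs had 5 of 35 members higher, 24 adjusted over the list alone, with a median of 1.95 (camera adjusted p = 3.18e-16, adjusted p = 0.273 with an estimated correlation). The ribosomal RNA mt-Rnr1 went from 8550 ± 3760 to 48200 ± 31700 CPM (2.49 ± 0.46, adjusted p = 0.00855, 6.14e-07 to 0.515 over the alternatives, the highest without RM palmitate replicates 2 and 3). Among other structured small RNAs, 3 of 7 rose, 6 adjusted over the list alone, with a median of 1.83 (camera adjusted p = 2.56e-06, adjusted p = 0.238 with an estimated correlation). A list of short RNAs other than snoRNAs, made after the data were seen, takes in mitochondrial transfer RNAs and miRNAs. Of 857 such features of at most 300 nt, 819 had positive values and 233 were called higher and 0 lower, 538 and 3 adjusted over the list alone, with a median of 1.75 (camera adjusted p = 1.19e-59, adjusted p = 0.104 with an estimated correlation). The 233 were 22, 27 and 122 without RM mock replicates 1, 2 and 3, and 589, 34 and 34 without RM palmitate replicates 1, 2 and 3. Of 18 cholesterol synthesis genes 6 fell and 0 rose, 11 and 0 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 1.43e-06, adjusted p = 0.0265 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis, had -1.47 ± 0.30 (adjusted p = 0.0106, 0.000793 to 0.316 over the alternatives, the highest without RM palmitate replicates 2 and 3). The markers of macrophages and lymphocytes had 1 of 3 tested members higher, the Fc receptor Fcgr3, also 1 adjusted over the list alone (median 0.92, camera adjusted p = 0.049, adjusted p = 0.238 with an estimated correlation). Ribosomal protein mRNAs had a median of 0.29 (6 of 81 higher, 9 adjusted over the list alone, camera adjusted p = 1.78e-06, adjusted p = 0.403 with an estimated correlation), which turned to -0.12 when scaled by total counts and was 0.46 and 0.17 without RM palmitate replicates 1 and 3. When RM palmitate replicates 2 and 3, which stood apart, were left out, the medians were 0.33 for H/ACA and 0.09 for C/D box snoRNAs, 0.88 for mitochondrially encoded RNAs, 0.61 for other structured small RNAs, 0.56 for the short features (1 higher), 0.04 for ribosomal protein mRNAs and 0.59 for macrophage and lymphocyte markers. The C/D, ribosomal protein and macrophage lists were then not past the threshold (camera adjusted p = 0.376, 0.31 and 0.103), the last also not without RM mock replicate 1 or 3 or RM palmitate replicate 1 or 3 (camera adjusted p = 0.0585 to 0.146).

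For RM in dataset B, 939 features were called, 633 higher and 306 lower, against 1114 by DESeq2, 907 higher and 207 lower. Scaling by total counts gave 2431, 433 higher and 1998 lower, and moved the median of all features by -0.37. The authors' deposited table holds 580 past its score, 575 higher and 5 lower. The count was 2671, 200 and 220 without RM palmitate replicates 1, 2 and 3, 197, 137 and 436 without RM mock replicates 1, 2 and 3, and 37 without both RM palmitate replicates 2 and 3.

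The interaction in dataset B had 0 features called by edgeR, with a smallest adjusted p of 0.078 and 2011 features at an unadjusted p under 0.05. DESeq2 called 375, 119 higher and 256 lower. The difference of palmitate effects, WT less RM, was 0.84 ± 0.22 for Snora23 (adjusted p = 0.12) and 1.32 ± 0.32 for Snord118 (adjusted p = 0.102). Of 37 H/ACA box snoRNAs, 21 had a more positive effect with WT adjusted over the list alone and 0 over all features, with a median of 0.94 (camera adjusted p = 2.8e-18, adjusted p = 0.262 with an estimated correlation). Histone mRNAs had a median of -1.21, 58 of 63 lower adjusted over the list alone and 0 over all features (camera adjusted p = 2.65e-49, adjusted p = 0.226 with an estimated correlation). Mitochondrially encoded RNAs had -2.49, 19 of 35 lower adjusted over the list alone and 0 over all features (camera adjusted p = 2.8e-18, adjusted p = 0.262 with an estimated correlation). The 857 short features other than snoRNAs had -1.57, 147 positive, 0 called by edgeR over all or adjusted over the list alone and 182 lower and 2 higher by DESeq2 (camera adjusted p = 1.8e-34, adjusted p = 0.14 with an estimated correlation). Without RM palmitate replicates 2 and 3 the histone, mitochondrial and short-feature medians were -0.72, -1.28 and -0.43 (camera adjusted p = 4.93e-17 and 1.36e-06 for the first pair). The mitochondrial median was -1.56 without WT mock replicate 1, and the short-feature median -0.95 without RM palmitate replicate 3. The count rose to 903 without RM palmitate replicate 1, was 110 without WT mock replicate 3, 5 without WT mock replicate 1 and 1 without WT palmitate replicate 1. Scaling by total counts gave 119, 95 higher and 24 lower, and moved the median of all features by 0.33.

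Between the mock groups of dataset B, 28 of 37 H/ACA box snoRNAs were lower with WT than with RM and 0 higher, 33 and 0 adjusted over the list alone, with a median of -1.34 (camera adjusted p = 7.12e-38, adjusted p = 0.0553 with an estimated correlation). Of 74 C/D box snoRNAs, 28 were lower and 0 higher, 36 and 0 adjusted over the list alone, with a median of -1.01 (camera adjusted p = 3.58e-21, adjusted p = 0.26 with an estimated correlation). Their summed share had a ratio of 0.84 (exact permutation p = 0.9), or 0.29, 1.13 and 1.10 without WT mock replicates 1, 2 and 3. Snord118 had 212 ± 25.7 CPM with WT and 1090 ± 222 with RM (-2.36 ± 0.24, adjusted p = 2.78e-05), and Snord33 had 16.6 ± 2.34 against 57.2 ± 6.31 (-1.78 ± 0.22, adjusted p = 0.000306). Anxa8, a calcium- and phospholipid-binding annexin, was higher with WT, 48.9 ± 4.02 against 8.92 ± 1.62 CPM (2.44 ± 0.16, adjusted p = 2.89e-07). Scd1, the stearoyl-CoA desaturase, was higher by 0.70 ± 0.11 (adjusted p = 0.000782). Histone mRNAs had 17 of 63 members higher with WT, 34 adjusted over the list alone, with a median of 0.72 (camera adjusted p = 3.52e-15, adjusted p = 0.289 with an estimated correlation). Cholesterol synthesis genes had 9 of 18 higher, 10 adjusted over the list alone (camera adjusted p = 0.000323, adjusted p = 0.0553 with an estimated correlation). Among fibroblast markers 2 of 14 were higher and 3 lower with WT, 3 and 3 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.603), and the surface glycoprotein Thy1 was higher by 1 ± 0.13 (adjusted p = 0.000273).

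edgeR called 1760 features here, 778 higher and 982 lower, and DESeq2 called 1608. The count was 878 without WT mock replicate 2, 941 and 736 without RM mock replicates 2 and 3, and 978 (372 higher, 606 lower) when scaled by total counts.

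Under palmitate in dataset B, Anxa8 again separated the genotypes, 41.5 ± 2.61 CPM with WT and 6.34 ± 1.78 with RM (2.77 ± 0.19, adjusted p = 1.15e-06), and Scd1 was higher with WT by 0.80 ± 0.11 (adjusted p = 0.000824). Among fatty acid response genes 4 of 18 were higher with WT, 9 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 1.69e-05, adjusted p = 0.255 with an estimated correlation). H/ACA box snoRNAs had 5 of 37 members lower with WT, 7 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 5.41e-07, adjusted p = 0.356 with an estimated correlation). C/D box snoRNAs had 5 of 74 lower, also 5 adjusted over the list alone, with -0.57 (camera adjusted p = 6.96e-08, adjusted p = 0.378 with an estimated correlation). Of 35 mitochondrially encoded RNAs, 9 were lower and 1 higher with WT, 21 and 1 adjusted over the list alone, with a median of -2.11 (camera adjusted p = 3.62e-10, adjusted p = 0.356 with an estimated correlation), where dataset A had a median of 2.02, a difference that was not tested. Of the 857 short features other than snoRNAs, 203 were lower and 2 higher with WT, 482 and 6 adjusted over the list alone, with a median of -1.60 (camera adjusted p = 2.68e-53, adjusted p = 0.188 with an estimated correlation). The 203 were 14, 31 and 91 without WT palmitate replicates 1, 2 and 3, and 554, 22 and 21 without RM palmitate replicates 1, 2 and 3. mt-Rnr1 (-3.24 ± 0.48, adjusted p = 0.00205) was not called without RM palmitate replicates 2 and 3, which stood apart (adjusted p = 0.237, the highest over the alternatives, the lowest being 1.92e-11). Epithelial markers had 1 of 2 tested members higher with WT, the keratin Krt19, also 1 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 0.0313, adjusted p = 0.256 with an estimated correlation). That call ended without WT palmitate replicate 3 or RM palmitate replicate 3 (medians 0.60 and 0.59). The epithelial median was 0.20 without RM palmitate replicates 2 and 3, with its test turned downward (camera adjusted p = 0.935), and the H/ACA and C/D medians were -0.17 and -0.13 (camera adjusted p = 0.138 and 0.154). The mitochondrial and fatty acid response medians were then -1.14 and 0.22 (camera adjusted p = 0.0119 and 0.0174), and the short features had -0.48 with 0 called. Neither of the 2 endothelial markers was called over all features or adjusted over the list alone (camera adjusted p = 0.556).

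The count was 974, 451 higher and 523 lower with WT, against 1071 by DESeq2, 342 higher and 729 lower, and 2109 when scaled by total counts, 1735 higher and 374 lower, with the median of all features moved by 0.36. It was 2500, 149 and 202 without RM palmitate replicates 1, 2 and 3, 112, 166 and 509 without WT palmitate replicates 1, 2 and 3, and 16 without both RM palmitate replicates 2 and 3.

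**Figure D3:**
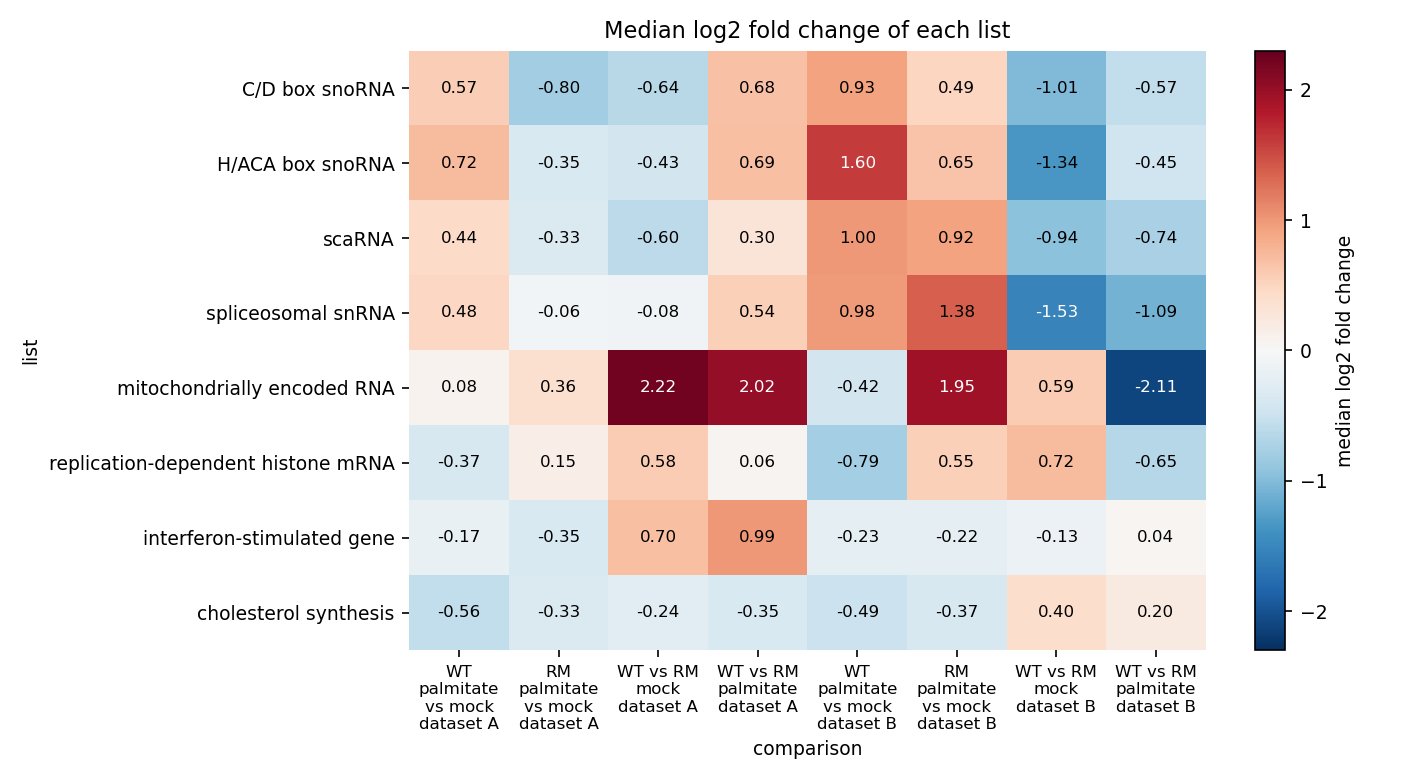
Median log2 fold change of 8 lists of RNAs and genes (y axis) in the palmitate and genotype comparisons of datasets A and B (x axis), with the value in each cell and red for positive and blue for negative medians. The H/ACA box snoRNA median was 1.60 for WT palmitate against mock in dataset B and -1.34 for WT against RM in mock of B.

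Averaged over datasets A and B, palmitate raised Ccn2 with WT by 2.56 ± 0.20 (adjusted p = 3.02e-09) and with RM by 2.56 ± 0.19 (adjusted p = 4.38e-10). Angptl4 rose by 2.26 ± 0.15 with WT (adjusted p = 4.6e-11) and by 2.35 ± 0.15 with RM (adjusted p = 1.42e-11). Nr4a1 rose by 2.25 ± 0.22 (adjusted p = 1.43e-07) and 2.41 ± 0.20 (adjusted p = 4.1e-09). With WT, 27 of 37 H/ACA box snoRNAs rose, 34 adjusted over the list alone, with a median of 1.18 (camera adjusted p = 2.7e-25, adjusted p = 0.147 with an estimated correlation). Of 75 C/D box snoRNAs 10 rose, 23 adjusted over the list alone, with a median of 0.77 (camera adjusted p = 3.52e-12, adjusted p = 0.488 with an estimated correlation). Snora64 rose by 1.18 ± 0.21 (adjusted p = 0.00109), Snora5c by 1.63 ± 0.28 (adjusted p = 0.000476) and Snord118 by 1.26 ± 0.25 (adjusted p = 0.00201). With RM, edgeR and DESeq2 each called 0 H/ACA and 0 C/D box snoRNAs, also 0 and 0 adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05, and the medians were 0.15 (camera adjusted p = 0.148) and -0.12 (camera adjusted p = 0.668). These averages take together medians of opposite sign, -0.35 and -0.80 in dataset A and 0.65 and 0.49 in dataset B. Of 18 cholesterol synthesis genes 13 fell with WT, 16 adjusted over the list alone (camera adjusted p = 3.98e-12, adjusted p = 0.00716 with an estimated correlation). With RM 5 of 18 fell, 8 adjusted over the list alone (camera adjusted p = 3.85e-07, adjusted p = 0.0304 with an estimated correlation). Of 63 histone mRNAs 17 fell with WT, 38 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 6.65e-17, adjusted p = 0.283 with an estimated correlation).

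For these averages edgeR called 1208 features with WT (766 higher, 442 lower; 1044 by DESeq2) and 1146 with RM (755 higher, 391 lower; 1100 by DESeq2). With WT the count was 728 without WT mock replicate 2 of A, 714 without WT palmitate replicate 3 of B, and 705 when scaled by total counts. With RM it was 685 and 584 without RM mock replicates 1 and 2 of A, 460 without RM palmitate replicate 3 of A, 572 and 630 without RM mock replicates 1 and 2 of B, and 625 and 579 without RM palmitate replicates 2 and 3 of B. Total counts as the scale gave 684 with RM, 316 higher and 368 lower, and moved the median of all features by -0.15.

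The averaged interaction had 0 features called by edgeR, 45 by DESeq2 (8 higher, 37 lower) and 1337 at an unadjusted p under 0.05, with a smallest adjusted p of 0.137. The palmitate effect was more positive with WT for 37 of 37 H/ACA box snoRNAs, 19 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 2.76e-20, adjusted p = 0.196 with an estimated correlation). It was also more positive for 74 of 75 C/D box snoRNAs, with a median of 0.82 (camera adjusted p = 1.2e-15, adjusted p = 0.28 with an estimated correlation). The count was 35 without RM palmitate replicate 1 of B, 8 without WT palmitate replicate 3 of A, and 1 without WT mock replicate 3 of B or without RM mock replicate 1 of B.

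Averaged over both datasets under palmitate, 4 of 18 interferon-stimulated genes were higher with WT than with RM over all features and 10 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.03e-05, adjusted p = 0.0152 with an estimated correlation). Ifit3 was higher by 2.19 ± 0.37 (adjusted p = 0.000654) and Ifit1 by 1.52 ± 0.33 (adjusted p = 0.00476). Dataset A alone gave 2.62 and 2.56, and in palmitate of C Ifit3 had 19 counts with WT and 79 with RM. Of 200 miRNAs 33 were lower with WT, 53 adjusted over the list alone. Their median was -1.01 (camera adjusted p = 3.03e-13, adjusted p = 0.543 with an estimated correlation), or -0.43 without RM palmitate replicates 2 and 3 of B. The 943 short features other than snoRNAs had -0.67, or -0.14 without these libraries and -0.43 without replicate 3 alone. Mir143 had -2.61 ± 0.54 (adjusted p = 0.00698, 1.55e-05 to 0.156 over the alternatives, the highest without RM palmitate replicates 2 and 3 of B). In all, 1318 features were called by edgeR, 703 higher and 615 lower, DESeq2 called 1247, and scaling by total counts gave 448, 174 higher and 274 lower. The count was 794 and 874 without WT palmitate replicates 2 and 3 of A, 694 without RM palmitate replicate 3 of A, 685 without WT palmitate replicate 1 of B, 835 and 689 without RM palmitate replicates 2 and 3 of B, and 224 without both of the last.

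Between datasets A and B, 23 features rose with palmitate and WT in both, where 2.7 would if the lists were independent, and 5 fell, against 0.7. With RM 22 rose in both, against 1.8, and 2 fell, against 0.5. The features called in all 4 palmitate comparisons included Angptl4, Hivep3, Ccn2, Baz1a, Samd4 and Skil, each higher. By a test of the difference, 24 features with WT had palmitate effects that differed between the datasets (15 more positive in B, 9 less, 146 by DESeq2). The 24 were 0 without WT mock replicate 3 or WT palmitate replicate 2 of A, WT mock replicate 1 or 2 of B or WT palmitate replicate 3 of B. They were 1 and 6 without WT mock replicate 1 of A and WT palmitate replicate 2 of B, and 245 and 180 without WT palmitate replicate 1 of A and WT mock replicate 3 of B. Nr4a1 was among them, with a difference of 2.46 ± 0.46 (adjusted p = 0.0322, 0.000347 to 0.126 over the alternatives, the highest without WT palmitate replicate 2 of A). With RM 1 feature, Ppp1r12b, differed (1.49 ± 0.23, adjusted p = 0.00847, 8.73e-05 to 0.376 over the alternatives, the highest without RM palmitate replicates 2 and 3 of B, and 0.0611, 0.052 and 0.0521 without RM mock replicate 3 of B, RM mock replicate 2 of A and RM palmitate replicate 1 of A), against 109 by DESeq2. The H/ACA box snoRNA response to palmitate with WT differed by a median of 0.73, B less A (0 of 37 called by edgeR or DESeq2, also 0 adjusted over the list alone, 7 at an unadjusted p under 0.05, camera adjusted p = 2.76e-07, adjusted p = 0.983 with an estimated correlation). With RM the median difference was 1.08 for H/ACA and 1.41 for C/D box snoRNAs (camera adjusted p = 7.73e-07 and 2.54e-11, adjusted p = 0.445 for both with an estimated correlation). They were 0.61 and 0.83 without RM palmitate replicates 2 and 3 of B, and edgeR called 0 of 37 and 0 of 75, also 0 and 0 adjusted over the list alone. The 943 short features other than snoRNAs had 1.38, or 0.20 without these libraries, 0.82 without replicate 3 alone and 0.83 when scaled by total counts.

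In dataset C, with 1 library per group and no test, C/D box snoRNAs were higher after palmitate with WT, 67 of 71 members, with a median log2 ratio of 0.92 at percentile 100 of matched random lists, the median of all 8830 features being 0.27. With RM the C/D median was -0.02, at percentile 0, beside 0.17 for all 13219 features. Their summed share of counts was higher after palmitate with both, 0.116% in mock (95% binomial interval 0.114 to 0.118) and 0.221% after palmitate (0.218 to 0.224) with WT, and 0.709% (0.704 to 0.714) and 1.28% (1.27 to 1.28) with RM. H/ACA box snoRNAs had a median of 0.30 with WT (percentile 73.18) and -0.93 with RM (percentile 0). The Rpl13a snoRNAs had 0.95 with WT (percentile 99.36) and -0.11 with RM (percentile 2), and the Dlk1-Dio3 RNAs 0.72 (percentile 98.09) with WT and -0.31 (percentile 0.45) with RM. The summed Dlk1-Dio3 share was again higher after palmitate with both, 0.0284% (0.0272 to 0.0297) and 0.0519% (0.0503 to 0.0535) with WT, and 0.0822% (0.0805 to 0.084) and 0.17% (0.167 to 0.172) with RM. Snord33 had 155 counts after palmitate and 65 in mock with WT, a log2 ratio of 1.19 (95% interval 0.77 to 1.64), and 432 and 534 with RM, -0.51 (-0.70 to -0.33). Snora23 had 27 and 32 counts with WT, -0.29 (-1.09 to 0.49), and 107 and 179 with RM, -0.94 (-1.31 to -0.59). Angptl4 had 66 and 8 counts with WT, 2.84 (1.93 to 4.26), and 776 and 79 with RM, 3.07 (2.76 to 3.44). Cholesterol synthesis genes had medians of -0.47 with WT and -0.34 with RM, both at percentile 0. Of the features called higher in both A and B with WT, 20 of the 20 that had a ratio in C were higher there, where 70% of all features were, and with RM 22 of 22 were, against 63.6%.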

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

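The tests of other short features, of depth without a library, of the PKR motifs by the interaction, of mitochondrial mRNAs, of scaling, of mitochondrial RNA in dataset B and of RNAs without a poly(A) tail and of histones with RM were chosen only after the result was seen, and the tests of depth by thinning, of S-phase genes and of other splits of the samples were not.

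The palmitate effect differed between datasets A and B for 24 features with WT and for 1 feature with RM, by the test of the difference itself. For WT, 5 of 60 splits of the samples gave as many calls, the highest of the other splits giving 972, and for RM 5 of 60 did, the highest giving 239, so chance was not excluded for either. Both highest splits exchanged mock and palmitate in B alone, which turns the difference of effects into their sum. With WT the count of 24 ranged from 0 to 245 without each library in turn, as listed above. With RM it was 0 without RM mock replicate 2 of A, RM palmitate replicate 1 of A or RM mock replicate 3 of B, and 10, 38 and 349 without RM palmitate replicate 2 of A, RM palmitate replicate 3 of A and RM palmitate replicate 1 of B.

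Of 37 H/ACA box snoRNAs 32 rose with palmitate and WT in dataset B, with a median of 1.60, and why the WT mock libraries lay below both RM groups for this class was not tested. Better recovery of short RNAs of every kind was argued against. The 857 other features of at most 300 nt had a median of -0.16 (95% interval -0.23 to -0.08). The 345 with mean counts of at least 50 had -0.40 (-0.42 to -0.33) and the 689 other than miRNAs 0.06 (-0.04 to 0.23). Without WT mock replicate 1 they were 0.16, -0.27 and 0.31, all below 0.5 of the snoRNA median (0.57, or 0.72 without it). Intervals of list medians in this section leave out the spread over libraries. Of the 857, 109 were higher and 8 lower, 106 and 5 adjusted over the list alone (camera adjusted p = 0.099, direction up), the 109 being 49 and 57 without WT mock replicates 1 and 2 and 66 and 36 without WT palmitate replicates 2 and 3, so better recovery of part of the short RNAs stays open. The 8 lower were 53 without WT mock replicate 3, and DESeq2 called 129 higher and 63 lower. Low depth of WT palmitate replicate 2, the shallowest, was argued against as the whole cause, since the H/ACA median without it was 1.63 (1.58 to 1.72). The totals of the WT groups overlapped with and without this library. Thinning keeps ratios, so no test by thinning is given. An action of palmitate through the RNA-binding motifs of PKR stays open, because the interaction of the H/ACA list had an adjusted p = 0.262 with an estimated correlation.

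Most mitochondrially encoded RNAs were higher with WT than with RM in dataset A, with a median of 2.22 in mock, while their summed share of counts was 1.82% against 1.32% (ratio 1.38, exact permutation p = 0.2). Better recovery of RNAs of transfer RNA size was argued against, since the 13 mitochondrial mRNAs had a median of 1.85 (95% interval 1.02 to 2.54). For scaling, the median under total counts was 2 (1.03 to 2.43), undecided since this crossed the bound of 1.11. A comparison by member, chosen only after that, gave a median excess of 0.87 (0.45 to 1.13) over 0.5 of each reported change. This argued against scaling as the whole cause. Loss of mitochondrial RNA with the mutated motifs stays open. Mock groups of B differed by a median of 0.59 (0.1 to 0.85, 35 features), or -0.18 without WT mock replicate 1. In mock of C mt-Nd5 had 10024 counts with WT and 980 with RM, the summed share being 3.32% and 3.7%.

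Of 63 histone mRNAs 27 fell with palmitate and WT in dataset B, with a list median of -0.79 (camera adjusted p = 8.36e-19, adjusted p = 0.207 with an estimated correlation). Lower recovery of all RNAs without a poly(A) tail was argued against. The 111 H/ACA and C/D box snoRNAs had a median of 1.15 (95% interval 1 to 1.34). Lower recovery of some stays open, the 345 short features above having -0.40. Fewer cells in S phase stays open, since 38 other S-phase genes had a median of -0.35 (-0.45 to -0.24). With RM these genes had -0.39 (-0.49 to -0.32) and the histone list 0.55 (0.44 to 0.64), but without RM palmitate replicates 2 and 3, which stood apart, they had -0.18 (-0.28 to -0.06) and -0.07 (-0.14 to 0.05), so the RM libraries do not decide it. Whether the RNA-binding motifs of PKR matter stays open, the interaction of the histone list having an adjusted p = 0.226 with an estimated correlation.

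For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real split was the 1 of 10 with as many calls in each. In dataset A the counts were 38 for WT palmitate against mock, 54 for RM palmitate against mock and 424 for WT against RM in mock, beside 0 as the highest of the other splits in each, and 388 for WT against RM under palmitate beside 39. In dataset B they were 1938 and 939 for palmitate with WT and RM and 974 for WT against RM under palmitate, beside 0 in each, and 1760 for WT against RM in mock beside 1. Over A and B, the real split was the 1 of 60 with as many calls, which alone does not exclude chance. Its counts were 1208 for WT palmitate (highest other 420), 1146 (228) for RM palmitate and 1318 (379) for WT against RM under palmitate. For the interactions, which had 0 calls, every split gives as many by construction (80 of 80 in dataset A, 80 of 80 in dataset B and 40 of 40 over both, the highest calling 1200, 1446 and 102), so nothing is decided.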

How the results depend on the processing

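The fits without RM palmitate replicates 2 and 3 of dataset B, those with 1 feature per near-identical set, the snoRNA list by the class in the files, the short features, and leaving out libraries for gene lists and class shares were chosen after seeing the data, and the other alternatives were not. Of the alternative counts of calls, 148 stayed within 1.5 times the reported count and 122 moved. Of the values of named genes, 1843 kept direction and side of the threshold, 108 were no longer past it, 19 came past it and 0 reversed. For single lists 1041 kept both, 225 were weaker and 10 reversed, and for dataset C 6 of 6 alternatives gave a like number of lists. RLE scaling and 1 feature per near-identical set moved no count of calls by over 1.5 times. Depth limits the shallow RM palmitate replicate 2 of dataset A most, and the cause of the changes below was not tested, except that fewer samples or features were fitted where the setting says so.

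Scaled by total counts, dataset A had 6 calls for WT palmitate, 12 for RM palmitate and 240 for WT against RM in mock. Dataset B had 1084, 2431, 119 for the interaction, 978 in mock and 2109 under palmitate. Over both there were 705 with WT, 684 with RM, 22 for the interaction, 448 for WT against RM under palmitate, and 49 (48 higher, 1 lower) and 4 (3 higher, 1 lower) for the effects by dataset with WT and RM, DESeq2 giving 58 higher and 51 lower for the latter. Total counts moved the median of all features by 0.15 and -0.45 in these and by -0.21 in the interaction of dataset A. Without a count filter, dataset A had 197, 349, 88 for the interaction, 723 in mock and 840 under palmitate, dataset B had 125 for the interaction, and both together had 13 for the interaction, 153 by dataset with WT and 33 with RM. With only the groups compared, there were 12, 14, 1552 and 133 calls in dataset A for WT palmitate, RM palmitate, WT against RM in mock and under palmitate. There were 276 and 244 in dataset B for RM palmitate and WT against RM under palmitate, and 585 and 467 for the same over both. DESeq2 gave 375 and 45 for the interactions of B and of both and 146 and 109 by dataset. Without RM palmitate replicates 2 and 3 of B there were 37 calls for RM palmitate and 16 for WT against RM under palmitate in B, 177 and 224 over both, and 0 by dataset with RM.

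Replicate numbers did not pair the samples: 4 of 18 pairs of libraries with the same number had correlated deviations over 0.1 in each dataset (-0.22 to 0.32 in A, -0.13 to 0.27 in B), and 5 of 12 libraries in each lay closest to their own number. With a replicate block there were 46 calls for the interaction in B, 1 for that over both, and 126 and 49 for the effects by dataset with WT and RM, and no other count moved by over 1.5 times.

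The PKR transcript had 221 alternatives with the same direction and side of the threshold, 33 weaker, 1 stronger and 14 reversed. Without RM palmitate replicates 2 and 3 of B it had -0.04 for RM palmitate in B, 0.09 for the interaction in B and -0.28 for WT against RM under palmitate in B. Over both it had 0.26 for RM palmitate, -0.37 for WT against RM under palmitate and -0.62 by dataset with RM (adjusted p = 0.46 to 0.99 for these 6). Scaled by total counts it had -0.55 for WT against RM under palmitate in B, 0.45 for RM palmitate over both, -0.70 for WT against RM under palmitate over both and -0.45 by dataset with RM (adjusted p = 0.061 to 0.569). With only the groups compared the first 3 of these had -0.97, 0.60 and -0.71 (adjusted p = 0.081 to 0.0973). For RM palmitate over both, RLE scaling gave 0.59 (adjusted p = 0.0538), 1 feature per near-identical set 0.60 (adjusted p = 0.05) and DESeq2 0.61 (adjusted p = 0.0673).

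Leaving out each library in turn, the PKR transcript ranged from -0.10 (without WT palmitate replicate 3) to 0.47 for WT palmitate in A. It ranged from -0.69 to 0.03 (without RM palmitate replicate 3) for the interaction in A, and from -0.27 to 0.11 (without RM mock replicate 2) for WT against RM in mock of A. In B it ranged from -0.04 (without WT palmitate replicate 2) to 0.13 for WT palmitate. It ranged from 0.37 to 0.96 (adjusted p = 0.00378, without RM palmitate replicate 1) for RM palmitate, and from -1.28 to -0.68 for WT against RM under palmitate. Over both it ranged from -0.04 (without WT palmitate replicate 3 of A) to 0.25 for WT palmitate, from 0.42 to 0.76 for RM palmitate and from -0.88 to -0.52 for WT against RM under palmitate. The effects by dataset ranged from -0.43 to 0.14 (without WT palmitate replicate 3 of A) with WT. With RM they ranged from -0.24 (without RM palmitate replicate 1 of A) to 0.42, also negative without RM mock replicate 2 of A and RM palmitate replicates 2 or 3 of B.

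The counts of calls without each library in turn ranged in A from 6 to 81 for WT palmitate, from 5 to 127 for RM palmitate, from 200 to 308 for WT against RM in mock and from 201 to 759 under palmitate. In B they ranged from 923 to 2154, from 137 to 2671, from 736 to 1826 and from 112 to 2500 in the same order, and from 0 to 903 for the interaction. Over both they ranged from 714 to 1279 for WT palmitate, from 460 to 1639 for RM palmitate, and from 0 to 35 for the interaction. They ranged from 685 to 1891 for WT against RM under palmitate, from 0 to 245 by dataset with WT and from 0 to 349 by dataset with RM.

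Over all comparisons 138 list calls were made, an estimated correlation left 9, and the other 28 alternatives stayed within 1.5 times. Without RM palmitate replicates 2 and 3 of B the histone median was -0.07 for RM palmitate in B, 0 for WT against RM under palmitate over both and -0.29 by dataset with RM. There the epithelial median was 0.20 for WT against RM under palmitate in B, with its test turned downward, and the miRNA median -0.19 by dataset with RM. Ribosomal protein mRNAs ranged from -0.09 (without RM palmitate replicate 3) to 0.27 for RM palmitate in A. For WT against RM under palmitate in A they ranged from -0.32 to 0.12 (without RM palmitate replicate 3), where H/ACA box snoRNAs ranged from 0.1 (without WT palmitate replicate 1, the test turning downward) to 1. In mock of B, miRNAs ranged from -0.04 to 2.08 and mitochondrially encoded RNAs from -0.18 to 0.85, both lowest without WT mock replicate 1. Total counts as the scale turned the ribosomal protein median for WT against RM under palmitate in B from -0.24 to 0.17 and the histone median by dataset with RM from 0.31 to -0.17.

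The ratio of C/D box snoRNA shares was 0.979 for WT palmitate and 1.09 for RM palmitate in B with mitochondrial and ribosomal RNA left out. Leaving out a library, it ranged in A from 0.95 to 1.66 for WT palmitate and from 0.996 to 1.79 for WT against RM under palmitate, both lowest without WT palmitate replicate 1. In B it ranged from 0.75 (without WT mock replicate 2) to 2.91 (without WT mock replicate 1) for WT palmitate. It ranged from 0.865 to 1.03 (without RM mock replicate 2) for RM palmitate and from 0.29 (without WT mock replicate 1) to 1.13 (without WT mock replicate 2) for WT against RM in mock. The H/ACA ratio for WT against RM under palmitate ranged from 0.813 (without WT palmitate replicate 1) to 1.33 in A and from 0.82 to 1.03 (without WT palmitate replicate 1) in B. The other 97 values of share ratios kept their direction. The short-feature median for WT palmitate in B was 0 with no count filter and ranged from -0.25 to 0.16 (without WT mock replicate 1).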

Other observations

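The fits without RM palmitate replicates 2 and 3 of dataset B and the list of short features were chosen only after the result was seen, and the other tests were not.

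Of 5 noncoding RNAs of the Dlk1-Dio3 cluster, 4 were lower with WT than with RM in mock of dataset B, also 4 adjusted over the list alone, with a median of -1.23 (camera adjusted p = 0.000279, adjusted p = 0.135 with an estimated correlation). Meg3 had -2.20 ± 0.41 (SE, edgeR adjusted p = 0.00976, 2.69e-08 to 0.0407 over the alternatives). Of 7 other structured small RNAs, 4 were lower with WT under palmitate in dataset B, the RNase MRP RNA Rmrp, the RNase P RNA Rpph1, the 7SK RNA Rn7sk and the vault RNA Vaultrc5, and 6 adjusted over the list alone, with a median of -2.24 (camera adjusted p = 3.52e-07, adjusted p = 0.255 with an estimated correlation). Without RM palmitate replicates 2 and 3 the median was -1.01. Of the 857 short features other than snoRNAs, 203 were lower and 2 higher under palmitate in dataset B. Their median was -1.60 (adjusted p = 0.188 with an estimated correlation), or -0.48 without those libraries.

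In dataset C, with 1 library per group and no test, Meg3 had 799 counts after palmitate and 271 in mock with WT, a log2 ratio of 1.5 (95% interval 1.31 to 1.71, counting error only). With RM it had 1705 and 2661 counts, -0.85 (-0.94 to -0.76).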
